A study of Alnus glutinosa with 15 samples.

How the data were processed

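The series holds 15 one-colour arrays of total RNA from *Alnus glutinosa*, in 5 groups of 3. Per the labels, the groups are non-inoculated roots at day 0 without nitrogen, non-inoculated roots at day 7 without nitrogen, non-inoculated roots at day 7 with nitrogen, roots at day 7 after inoculation with *Frankia alni* without nitrogen, and nodules at day 21. Each custom Agilent array carried 14445 spots: 13909 probes of 60 nt with 13780 distinct sequences, 459 positive control spots and 77 negative control spots. The labels do not say whether the replicates of a group came from separate plants or separate cultures. Their spread may be technical, and the p-values measure only the spread between these samples.

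The deposited text files, 1 per array, give intensity: the scanner mean of each spot, the median of its local background, and a processed signal after background subtraction and detrending. Per the file headers, Agilent Feature Extraction 9.5.1.1 produced this intensity and replaced low signals with a surrogate value, while the labels name version 9.1. No scaling between arrays was applied to these values. The value table deposited by the authors covers 12399 probes and holds a ratio. Its values equalled the processed signal times 1 factor per array and 1 factor per probe for 99.98% of values of bright probes, within 0.0001 log2, and for 93.7% of all values. The probe reference behind this ratio is not stated, and only 0.355% of probes had a median of 1 across the arrays. Column medians of the ratio, replicates 1 to 3, were 0.985, 1.04 and 1.03 in roots at day 0, 0.996, 1.07 and 0.962 in non-inoculated roots at day 7 without nitrogen, 0.887, 0.871 and 0.859 with nitrogen, 0.975, 1.06 and 1.06 in inoculated roots, and 1.02, 1.01 and 0.980 in nodules. The array factors departed from the 75th percentile factors by up to 0.20 log2. The table lacked 1510 probes, of which 13 were well above background on 1 array and 0 on more.

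The processed signals were log2 transformed and each array was centred on its 75th percentile, so that a level of 0 is the 75th percentile of the array. Spots marked as outliers by the image software were left out (58 spots over all arrays, 33 of them on replicate 2 of the roots with nitrogen), and 0 spots were saturated. A probe was tested when the image software called it well above background on all 3 arrays of at least 1 group. This kept 11008 probes and left out 2901, and 1512 probes were well above background on no array. The 75th percentile of the signal ranged from 2041 to 3494 between arrays. Of 13909 probes, 10891 ± 168 (mean ± SD, n = 3) were well above background in nodules, 10433 ± 367 in inoculated roots, 10474 ± 166 in roots at day 0, 10293 ± 339 in non-inoculated roots at day 7 without nitrogen and 9807 ± 282 with nitrogen. Pairs of IDs that share a sequence measured the precision of a spot: over 71 such pairs the difference in log2 had an SD of 0.10. The number of arrays limits the precision of a group mean.

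Linear models with moderated t tests (limma 3.58.1 in R 4.3.3) were fitted to all 15 arrays with 1 mean per group and 10 residual degrees of freedom. A probe was called at a Benjamini-Hochberg adjusted p below 0.05. The 5 comparisons were inoculated against non-inoculated roots at day 7, nodules against roots at day 0, nodules against inoculated roots at day 7, roots without against with nitrogen at day 7, and roots without nitrogen at day 7 against day 0. Shared calls between comparisons were counted against the count expected for independent lists, n1×n2/N. For the pair of comparisons with a common control, data sets with no difference between groups were also simulated (50 times). The shares of tested probes whose arrays did not overlap between groups are given beside the share of 10% that chance gives for 3 against 3 arrays. Where a probe was above background on no array of 1 group, that group was set to the lowest signal well above background on each array, and the fold is written as "at least". Sums of probes past 8-fold or 100-fold used these bounds and left out probes above background on no array of either group. Calls and counts at 2-fold used the fitted change and can include such probes, whose number was not counted. Where a named probe was above background on 1 or 2 arrays of the lower group, its other arrays were set in the same way after the probes had been chosen by their fitted change, and the fold is also written as "at least".

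The comparisons, the scaling, the filter, the thresholds, most alternatives and the rule for named probes were chosen before the data were examined. The rule took, per comparison and direction, the 2 called probes with the largest fold among those with no overlap between the arrays of both groups. Other probes are named only where the text says that they were chosen after their values were seen. Probes are given by ID and, except for AG-R01f_035_P21, AGCL545Contig1, AGCL726Contig1 and AG-R01f_025_K08, by sequence. All probes carry the description "Unknown", and 0 of their IDs occur in the reference table of 32175 genes. For this reason 0 of 25 lists of genes fixed before the data were examined matched a probe. Tests of gene lists and of cell type markers were therefore not run.

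The procedure was tested on simulated data in which 200 of 11008 probes were changed, 50 for each fold. Recovery at 1.5-fold was 48% for inoculation, 42% for nodules against day 0, 40% for nodules against inoculated roots, 36% for nitrogen and 50% for time. At 2-fold it was 72%, 72%, 74%, 78% and 80%, and at 8-fold 98%, 100%, 96%, 94% and 100%. Unchanged probes made up 6.59%, 5%, 2.61%, 1.94% and 6.98% of the calls.

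Alternatives were normexp background correction of the mean signals (offset 50), quantile normalization, scaling to the median of 7 of 10 spike-in probes with 20 spots each, centring on the median of 8810 probes well above background on all arrays, no filter, a stricter filter, a floor for low signals, outlier spots kept, a variance trend, only the 6 arrays compared, the replicate number or the slide as a block, the value table of the authors, an adjusted p of 0.01, a minimum of 2-fold, non-inoculated roots at day 7 as the control of nodules, and each array left out in turn. The arrays came from 2 slides with 8 and 7 arrays, and each slide held all groups. Slide 1 held 1 array of nodules and 1 of roots at day 0, and slide 2 held 1 array of each day 7 group. Such an array was taken to vary like the other groups. Nodules against day 0 on slide 1, and inoculation and nitrogen on slide 2, thus set 1 array against 1. Sequence words of 3 bases were compared by logistic regression with 5 cross-validation folds (scikit-learn 1.9.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9.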

Results

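Black alder (*Alnus glutinosa*) forms root nodules with the nitrogen-fixing actinobacterium *Frankia alni*. Plants starved of nitrogen for a week were either inoculated or not, and a further group received nitrogen again. Roots were sampled at day 0 and day 7, and nodules at day 21, with 3 arrays per group. Nitrogen supply and nodule tissue set the largest differences apart. The first principal component held 59.4% of the variance and separated the roots with nitrogen (101.0 to 114.6) from all other arrays (-33.7 to -18.9). Nodules stood apart on the next component, which held 25.4%. Replicates of a group correlated with r of 0.984 to 0.995 across the 8810 probes well above background on all arrays. Dim probes are left out of this r, and probes are not independent replicates.

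**Figure D1:**
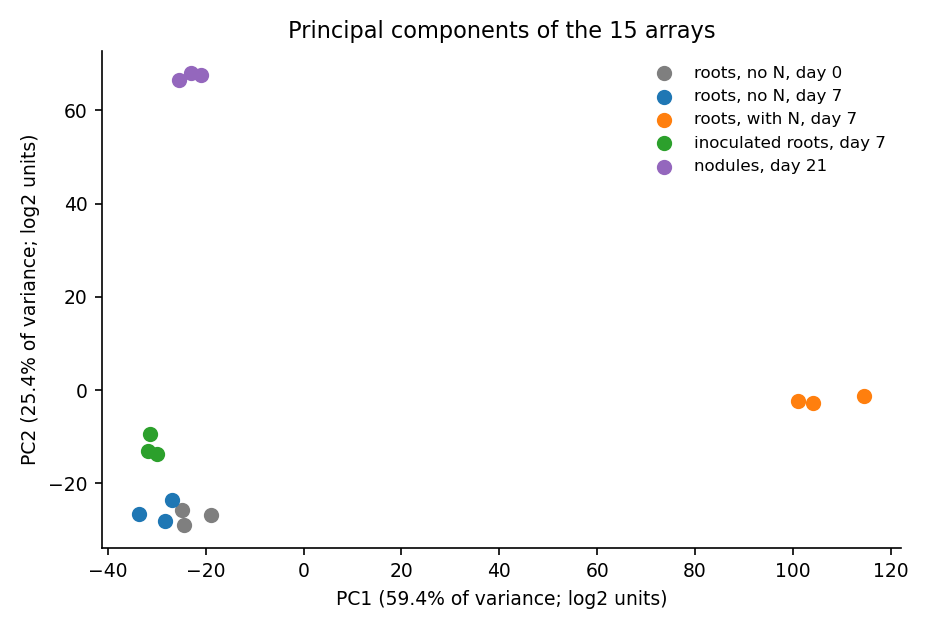
Principal components of the 15 arrays, from probes well above background on all of them. The first component held 59.4% and the next 25.4% of the variance.

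Detection alone also set nodules apart, though they are the only tissue other than roots, and each root group is set against other root groups. In nodules 203 probes were well above background on all 3 arrays and on no other array of the series. The corresponding count was 33 in roots with nitrogen, 5 in inoculated roots, 4 in roots at day 0 and 0 in non-inoculated roots at day 7 without nitrogen. Roots with nitrogen lacked the most: 108 probes were well above background on all 12 other arrays and on no array of that group, against 10 in nodules. The mean 75th percentile of the signal was highest in nodules (3265) and lowest in roots with nitrogen (2262). How far brightness shaped these counts was not tested.

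The median level of a set of 305 probes, the co-varying set, was lowest on replicate 1 of each day 7 root group. These probes were chosen after the data were seen, as those at least 8-fold lower on replicate 1 of the non-inoculated roots without nitrogen than on replicates 2 and 3. Their median level on those arrays was -8.43, -2.89 and -2.36. With nitrogen, replicate 1 was also low (-8.77, -5.80 and -5.49), and inoculated roots stood at -7.92, -5.85 and -5.15. Well above background on replicates 1 to 3 were 14, 141 and 157 of the 305 with nitrogen, and 66, 181 and 221 in inoculated roots. Not every member followed the median: AG-R01f_035_P21 was above background on no array of either group. Roots at day 0 lay near background (-8.73, -9.31 and -9.31), and nodules were steady at -5.37, -6.01 and -5.68. Probes with IDs beginning AG-R made up 61.3% of the set and 31.0% of the array. Of the set, 180 probes passed the filter and entered the tests, and their share is given beside each result below.

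**Figure D2:**
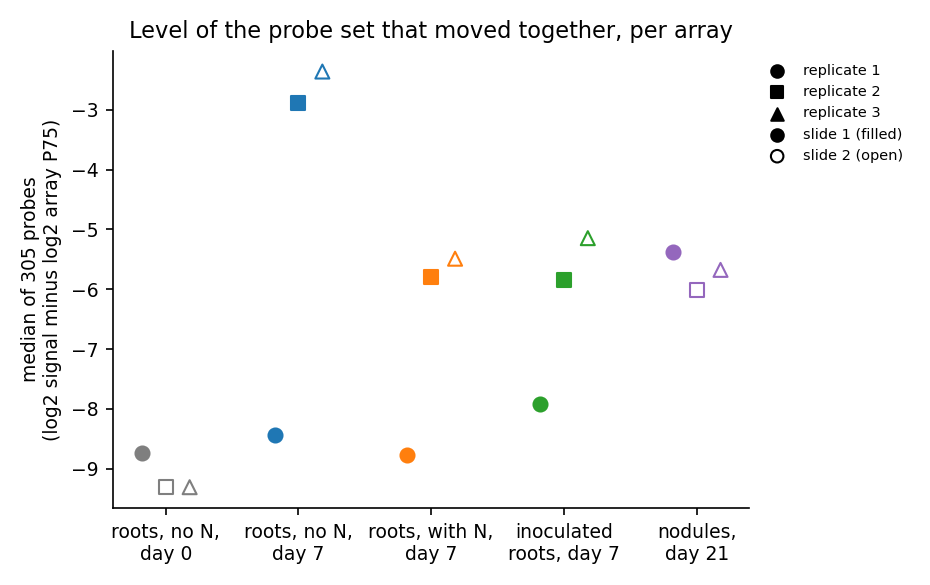
Median level of the 305 co-varying probes on each array, relative to the 75th percentile of the array. Non-inoculated roots at day 7 without nitrogen ranged from -8.43 to -2.36.

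Which transcripts had responded to *Frankia* within a week was read from inoculated against non-inoculated roots at day 7. Of 11008 probes, 961 (8.73%) changed, 618 upward and 343 downward. Increases were also the larger ones. Of those that rose, 330 did so at least 2-fold and 58 at least 8-fold, against 91 and 4 of those that fell. A group of 104 probes rose from no detection on any non-inoculated array to detection on all 3 inoculated arrays. Of these 104, 82 were above background on no array at day 0, 92 on no array with nitrogen, and 97 on all 3 nodule arrays.

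The largest increase after inoculation was that of AGCL960Contig1 (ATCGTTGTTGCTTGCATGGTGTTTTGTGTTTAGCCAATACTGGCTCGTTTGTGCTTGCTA), at least 695-fold (adjusted p = 3.90e-08). Its level went from -8.74 ± 0.29 to 2.93 ± 0.96 (mean ± SD, n = 3) and was 3.20 ± 0.29 in nodules. AGCL115Contig1 (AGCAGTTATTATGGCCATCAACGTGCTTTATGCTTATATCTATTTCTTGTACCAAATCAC) rose at least 287-fold (adjusted p = 1.90e-08), from -8.55 ± 0.41 to 1.65 ± 0.33, with 1.75 ± 0.34 in nodules. Among the decreases was AG-N01f_013_J18 (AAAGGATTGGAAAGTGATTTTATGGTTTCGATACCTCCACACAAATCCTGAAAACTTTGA), which dropped 14.7-fold (log2 change -3.88 ± 0.62 SE, adjusted p = 0.00188). Its level was 0.22 ± 0.37 in non-inoculated roots, -3.66 ± 1.07 in inoculated roots and -7.00 ± 1.42 in roots with nitrogen. AG-R01f_035_P21, a member of the co-varying set, fell at least 14-fold (adjusted p = 0.0386) from a level that varied widely between non-inoculated arrays (-2.78 ± 4.79), and it lost the call in 6 of 11 refits. No other call of this comparison belonged to the set.

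Over all 11008 probes, 27.4% had no overlap between the arrays of both groups, against 10% by chance. With the slide as a block 954 probes were called, on slide 1 alone 195 and on slide 2 alone 473. With each array left out in turn, 433 to 532 probes rose and 208 to 335 fell. The fits above pooled the residual spread over all groups. The SD of the log2 difference between replicates was 0.28 to 0.40 in the groups compared here. It was 0.22 to 0.32 in nodules and roots at day 0, and 0.34 to 0.41 with nitrogen. With only the 6 arrays compared, 489 probes were called, 395 upward and 94 downward. Nodules against day 0 gained calls in such a fit, and every other comparison lost some. How far spread or fewer degrees of freedom lowered the count was not tested. Scaling to the spike-ins left 278 calls, 91.0% of them upward, against 64.3% here and 76.5% in the value table of the authors. The spike-ins varied between replicates relative to the 75th percentile. Their log2 difference had an SD of 0.64 in non-inoculated roots at day 7 without nitrogen and 0.25 with nitrogen. It was 0.41 in inoculated roots, 0.35 in roots at day 0 and 0.098 in nodules. This spread enters every result with spike-in scaling, and how far it lowered the counts was not tested.

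What set nodules apart from roots before inoculation was read from nodules against roots at day 0, a control sampled 21 days earlier. Here 6558 probes (59.6%) differed, 2849 higher in nodules and 3709 lower. Strong increases far outnumbered strong decreases: 644 probes were at least 8-fold higher and 139 at least 8-fold lower, and 194 against 8 passed 100-fold. Of the probes that rose, 505 were above background on no array at day 0, and 101 probes above background on all 3 arrays at day 0 were lost in nodules. The co-varying set supplied 129 of the 2849 increases and 97 of the 644 past 8-fold. Without it 547 probes rose at least 8-fold and 186 at least 100-fold.

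AG-N01f_014_L13 (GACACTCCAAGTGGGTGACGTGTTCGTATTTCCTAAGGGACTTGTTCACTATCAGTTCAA) rose at least 6252-fold in nodules (adjusted p = 1.04e-10), to 5.44 ± 0.15. AG-N01f_008_E02 (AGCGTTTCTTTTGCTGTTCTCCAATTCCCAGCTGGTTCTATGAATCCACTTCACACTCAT) rose at least 5357-fold (adjusted p = 2.70e-11), to 5.22 ± 0.20. Neither was above background in non-inoculated roots, and both were detected on all 3 arrays of inoculated roots, at -3.72 ± 0.67 and -4.11 ± 0.70. AG-R01f_037_A23 (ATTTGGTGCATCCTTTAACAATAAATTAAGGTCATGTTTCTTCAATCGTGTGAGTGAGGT) fell at least 1812-fold (fitted log2 change -11.17 ± 0.67 SE, adjusted p = 3.04e-08), from 4.21 ± 0.16 to -6.96 ± 0.83. AG-R01f_021_P13 (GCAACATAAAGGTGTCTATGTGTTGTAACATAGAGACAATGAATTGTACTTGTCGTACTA) fell 337-fold (log2 change -8.40 ± 0.44 SE, adjusted p = 9.12e-09). Both of the latter were also low in roots with nitrogen, at -3.92 ± 0.71 and -2.60 ± 0.68, and intermediate in inoculated roots, at 0.69 ± 1.5 and 0.96 ± 0.73.

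**Figure D3:**
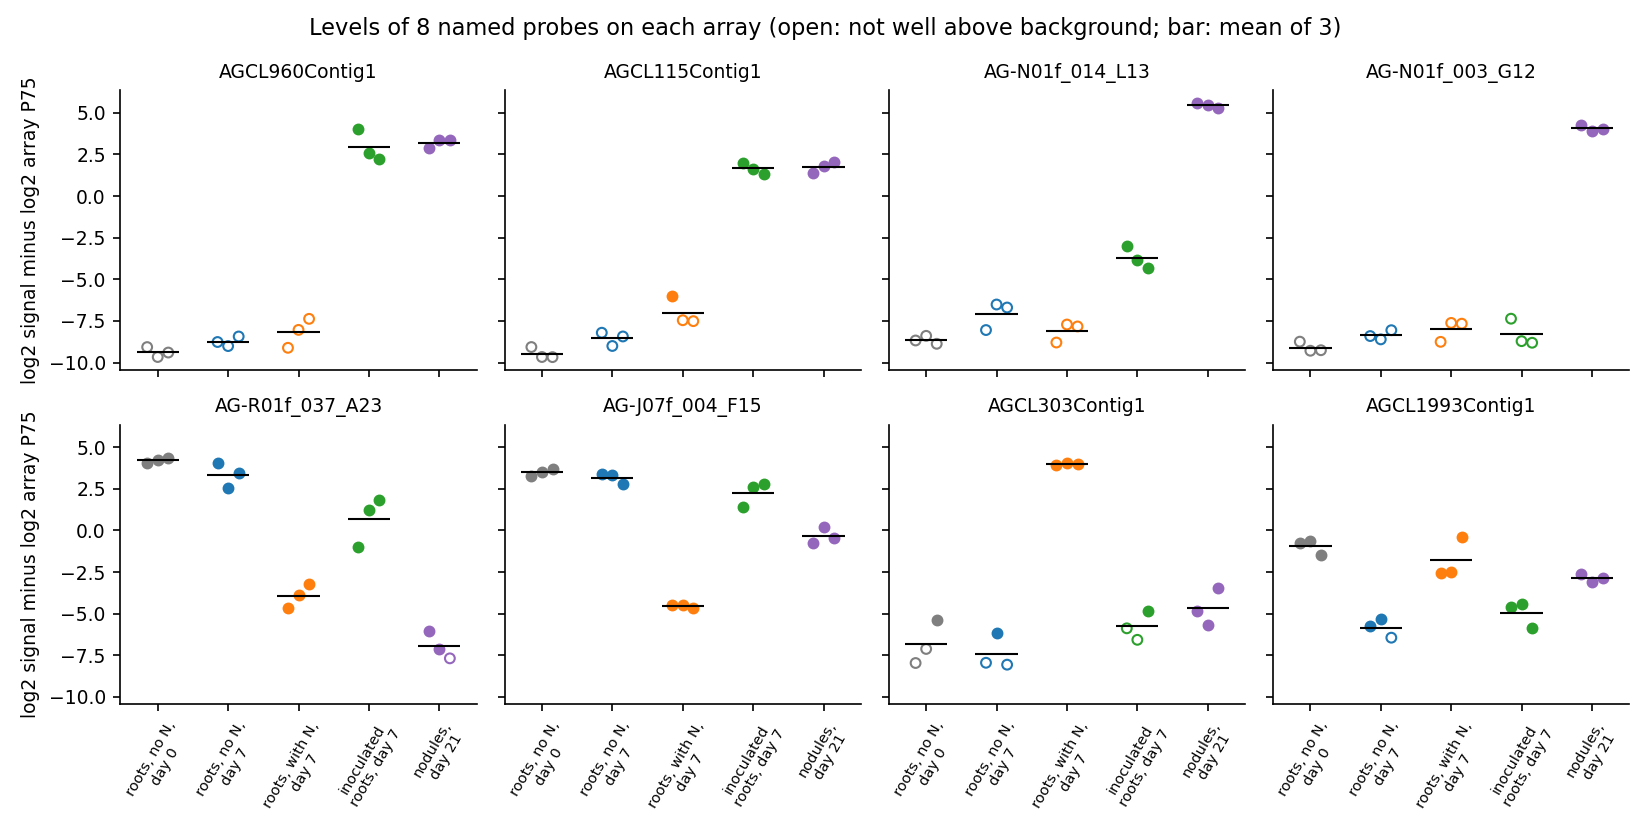
Levels of a selection of the named probes in the 5 groups, relative to the 75th percentile of each array. AG-N01f_014_L13 reached 5.44 in nodules and AG-R01f_037_A23 stood at 4.21 in roots at day 0.

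Without overlap were 70.7% of all tested probes, against 10% by chance. Against non-inoculated roots at day 7 without nitrogen 6193 probes were called, and 4768 of the 6558 calls were kept in the same direction. A slide block gave 6551 calls, slide 1 alone 2792 and slide 2 alone 5852. Over the 8810 probes above background on all arrays, on which such shifts are measured throughout, the scaling left the median probe at -0.15 log2 in nodules, and with spike-in scaling it stood at 0.07, with 2898 calls of which 64.4% were higher in nodules, against 43.4% here.

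Whether early changes persisted in nodules was examined by comparing the lists of inoculation at day 7 and of nodules against day 0, which share no array. Of the 618 probes that rose early, 442 were higher in nodules, 63 lower and 113 not called. Of the 343 that fell early, 246 were lower in nodules, 27 higher and 70 not called. Thus 688 probes changed the same way, 442 upward (160 expected for independent lists) and 246 downward (116 expected), and 90 changed in opposite directions. The overlap was complete among strong responses: all 58 probes that rose at least 8-fold by day 7 were higher in nodules. Across all probes the changes correlated with r = 0.384, and 0.538 without the co-varying set, with probes not being independent replicates. Without replicate 1 of the non-inoculated roots at day 7 without nitrogen, 441 probes changed the same way and 106 in opposite directions, with r = 0.205. Of the early increases in that refit, 329 were higher in nodules (114 expected) and 38 lower (144 expected). The early decreases depended more on that array: 112 were lower in nodules (71.7 expected) and 68 higher (56.4 expected).

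**Figure D4:**
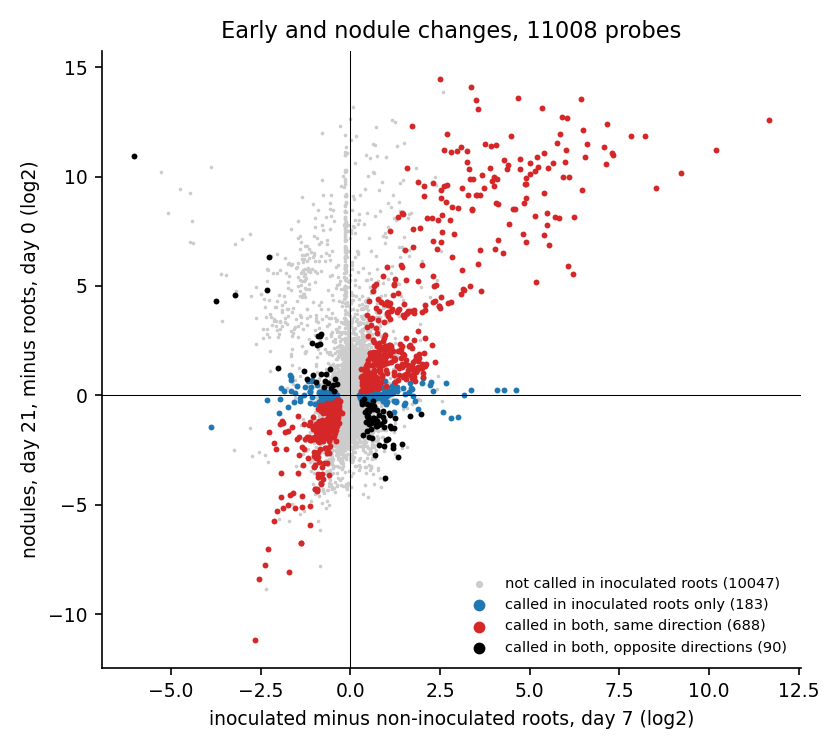
Change by inoculation at day 7 against the change in nodules relative to day 0. Of the probes called in both, 688 moved the same way and 90 in opposite directions.

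How nodules differed from roots a week after inoculation was read from nodules against inoculated roots at day 7. Tissue and day differ together here. The labels hold no root at day 21 and no nodule at day 7, so timing cannot be told apart from tissue. In nodules 2328 probes were higher and 3366 lower (5694 in all, 51.7%). At least 8-fold changes were again mostly increases, 461 against 81, and 325 probes rose from no detection on the inoculated arrays. Of the 547 probes at least 8-fold up in nodules over day 0 outside the co-varying set, 204 had already risen by day 7 after inoculation, 3 had fallen and 340 were not called. Of the 186 past 100-fold, 106 had already risen. Of the 58 strong early responders, 51 were higher again in nodules than in inoculated roots and 7 were not called. Among all 618 early increases the split was wider: 303 were higher in nodules than in inoculated roots, 159 lower and 156 not called, although these comparisons share the inoculated arrays.

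AG-N01f_003_G12 (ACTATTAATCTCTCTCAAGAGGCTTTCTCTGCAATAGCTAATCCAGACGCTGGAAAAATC) rose at least 1625-fold over inoculated roots (adjusted p = 3.75e-10), to 4.08 ± 0.20. AG-N01f_040_G23 (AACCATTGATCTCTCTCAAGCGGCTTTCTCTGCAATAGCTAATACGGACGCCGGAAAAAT) rose at least 1418-fold (adjusted p = 2.29e-09), to 3.88 ± 0.27. Both were above background on nodule arrays only. Their sequences share 53 of 59 aligned bases, so 1 transcript may have bound both. AG-R01f_037_A23 fell at least 158-fold (fitted log2 change -7.65 ± 0.67 SE, adjusted p = 1.42e-06), and AGCL1854Contig1 (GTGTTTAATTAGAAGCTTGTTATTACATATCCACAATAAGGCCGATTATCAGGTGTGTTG) fell at least 38.5-fold (fitted log2 change -6.17 ± 0.63 SE, adjusted p = 5.01e-06). The co-varying set held 10 of the increases and 1 of the decreases.

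For 61.9% of all tested probes the arrays did not overlap, against 10% by chance. The count was 5627 with a slide block, 2747 on slide 1 and 4250 on slide 2. The median probe lay at -0.16 log2 in nodules, and at 0.17 with spike-in scaling, which left 2428 calls, 70.9% higher in nodules, against 40.9% here and 51.9% with median centring.

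Nitrogen supply was tested between non-inoculated roots at day 7. Between roots without and with nitrogen at day 7, 7473 probes (67.9%) differed, 4713 higher without nitrogen and 2760 higher with it. The strongest differences ran the other way. Probes at least 8-fold higher with nitrogen numbered 540, against 182 higher without, and past 100-fold there were 61 against 11. Of the probes higher with nitrogen, 125 were above background on no array without it. The reverse held for 168 of those higher without nitrogen.

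AGCL303Contig1 (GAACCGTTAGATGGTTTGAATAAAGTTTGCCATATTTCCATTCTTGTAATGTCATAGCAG) was at least 1265-fold higher with nitrogen (fitted log2 change without against with nitrogen -11.37 ± 0.73 SE, adjusted p = 4.20e-08). AG-R01f_033_A10 (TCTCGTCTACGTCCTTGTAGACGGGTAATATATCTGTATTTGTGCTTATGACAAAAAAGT) was at least 1244-fold higher with nitrogen (adjusted p = 2.38e-10), at 3.77 ± 0.53. In nodules, which grew without nitrogen, their levels were -4.65 ± 1.12 and -4.93 ± 0.89. Higher without nitrogen were AG-N01f_018_O02 (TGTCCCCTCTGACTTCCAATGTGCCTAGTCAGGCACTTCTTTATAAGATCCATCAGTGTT), at least 168-fold (fitted 7.72 ± 0.23 SE in log2, adjusted p = 1.39e-10), and AG-J07f_004_F15 (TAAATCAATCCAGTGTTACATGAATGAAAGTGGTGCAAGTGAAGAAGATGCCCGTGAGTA), 210-fold (7.71 ± 0.33 SE, adjusted p = 1.25e-09). AG-N01f_018_O02 stayed at 1.09 ± 0.36 in nodules, while AG-J07f_004_F15 stood at -0.33 ± 0.49 there and at 3.49 ± 0.21 in roots at day 0.

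The co-varying set held 18 of the probes higher without nitrogen, 7 of them past 8-fold, and none of those higher with it. No overlap was seen for 70.0% of all tested probes (10% by chance), and 7464 were called with a slide block, 6276 on slide 1 and 5580 on slide 2. The median probe was 0.23 log2 higher without nitrogen, 0.07 with normexp background correction and 0.88 with spike-in scaling, where 81.5% of calls were higher without nitrogen, against 63.1% here.

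Whether inoculation moved roots toward the state of roots with nitrogen was examined by setting both lists side by side, with the nitrogen change read as with against without. Of the probes that rose with inoculation, 204 were higher with nitrogen (155 expected for independent lists) and 192 lower (265 expected). Of those that fell, 174 were lower with nitrogen (147 expected). Those that fell and were higher with nitrogen also exceeded the number expected, 86.0. In all 378 probes changed the same way and 310 in opposite directions, and with spike-in scaling the balance turned, 44 against 47. Both comparisons use the same 3 non-inoculated arrays, which are too few to be split into separate controls, so part of the excess may come from the shared control. Simulated data with no difference gave 0 shared calls, r = 0.498 and a covariance of 0.0642. With no probe changed, hardly any calls could arise to be shared. The 0 therefore cannot show how many shared calls a common control adds where many probes change. The simulation drew each probe independently with the same spread in all groups. In the shared control the co-varying set moved together, at -8.43, -2.89 and -2.36, and this pair was not refitted without it. The simulated covariance therefore cannot show how much of the observed one the shared control gives. The observed r was 0.132 and the covariance 0.166, which is 0.102 above the simulated mean, with probes not being independent replicates. Without replicate 1 of the shared control they were 0.270 and 0.420, with 279 probes changed the same way and 151 in opposite directions, and without replicate 3 r was 0.0885.

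Continued nitrogen starvation was followed from day 0 to day 7 in non-inoculated roots, where plant age and longer starvation cannot be told apart. In this comparison 2622 probes (23.8%) changed, 1347 upward and 1275 downward. The increases past 8-fold were almost all of the co-varying set, 86 of 87, and the set supplied 121 of the 1347 increases in all. Outside it 1226 probes rose, 233 of them at least 2-fold, and 1275 fell, 404 at least 2-fold and 22 at least 8-fold. The calls and 2-fold counts include probes above background on no array at either day, such as AG-N01f_008_E02 (fitted log2 change 2.65).

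AGCL1993Contig1 (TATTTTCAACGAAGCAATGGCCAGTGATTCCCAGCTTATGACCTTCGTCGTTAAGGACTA) fell at least 27.3-fold (fitted log2 change -4.88 ± 0.55 SE, adjusted p = 0.000155), and AGCL531Contig1 (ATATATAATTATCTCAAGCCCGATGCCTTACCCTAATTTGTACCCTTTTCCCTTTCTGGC) fell 23-fold (-4.53 ± 0.53 SE, adjusted p = 0.000204). Inoculated roots at day 7 were low too, at -4.96 ± 0.77 and -3.70 ± 0.75, and nodules less so, at -2.85 ± 0.21 and -1.47 ± 0.13. The largest increases, AGCL545Contig1 (at least 93.3-fold, fitted 7.65 ± 2.26 SE in log2, adjusted p = 0.0293) and AGCL726Contig1 (183-fold, 7.52 ± 2.00 SE, adjusted p = 0.0189), belong to the co-varying set and had an SD of 4.62 and 4.05 between the day 7 arrays, and each lost the call in 5 of 11 refits. The single increase past 8-fold that did not meet the criterion of the set was AG-R01f_025_K08, chosen after its values were seen, at least 33.0-fold (adjusted p = 0.000810). It followed the set elsewhere, at -8.66, -4.83 and -4.72 with nitrogen and -7.95, -5.18 and -4.46 in inoculated roots.

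Arrays did not overlap for 44.8% of all tested probes, against 10% by chance. With a slide block 2517 were called, on slide 1 alone 26 and on slide 2 alone 1852. With each array left out in turn, 838 to 1114 probes rose and 868 to 1126 fell. Spike-in scaling left 469 calls, 23.7% upward, against 51.4% here and 39.9% in the value table of the authors. It also shifted the median probe from 0.01 to -0.24 log2.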

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

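The count of strong changes with every dim array bounded, and the refits without the co-varying probes, with 1 ID per sequence, on single slides and without both replicate 1 arrays of the non-inoculated roots at day 7 were chosen after the data were seen. The counts that moved more than 1.5 times from 961, 6558, 5694, 7473 and 2622 follow. Probes named by the rule were refitted in 11 of the settings each, and none reversed there. For inoculation the count was 371 with normexp correction, 278 with spike-in scaling, 489 with only the 6 arrays compared, 195 on slide 1, 473 on slide 2, 428 at an adjusted p of 0.01 and 421 with a minimum of 2-fold. For nodules against day 0 it was 2898 with spike-in scaling, 2792 on slide 1 and 3028 at 2-fold. For nodules against inoculated roots it was 2428, 2747 and 2534. For nitrogen only the 2-fold minimum moved the count, to 3764. For time it was 1284 with normexp correction, 469 with spike-in scaling, 26 on slide 1, 1245 at 0.01 and 758 at 2-fold. Stricter thresholds call fewer probes by construction, and single slides hold fewer arrays. For the other settings the cause was not tested. Shared calls of early and nodule responses were 256 with normexp correction and 230 with spike-in scaling, and those of inoculation and nitrogen 159 and 44.

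Setting every dim array of the lower group to its lowest detected signal left 54 increases and 3 decreases past 8-fold for inoculation, 637 and 134 for nodules against day 0, 450 and 77 against inoculated roots, 170 and 532 for nitrogen, and 87 and 18 for time.

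With each array left out in turn the counts ranged over 648 to 867, 5832 to 5962, 4968 to 5298, 7036 to 7294 and 1753 to 2146. Shared calls ranged over 441 to 669 and 260 to 396. Without the co-varying probes the counts were 980, 6432, 5710, 7463 and 2460, and without both replicate 1 arrays 788, 6494, 5582, 6975 and 2053. Probes named by the rule and outside the set were called in the same direction in 187 of 187 refits, and the 3 named probes of the set lost the call in 16 of 33. The rule had chosen the former from the same data for their large changes without overlap, so kept calls were likely from the outset. AG-R01f_025_K08 was not among the refitted probes.

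The replicate block gave 863, 6465, 5584, 7409 and 2561 calls and 617 and 352 shared calls. Deviations of each array from its group mean were correlated over the 8810 probes well above background on all arrays. Arrays with the same number had a median r of -0.01, 0.04 and 0.05 (lowest -0.28, -0.22 and -0.15), against -0.02 for different numbers, and 7 of 15 correlated best with their own number. These probes leave out most of the co-varying set: 16 of 305 were above background on replicate 1 of the non-inoculated roots at day 7 without nitrogen. The correlations therefore cannot show the link by number of that set, whose median level was lowest on replicate 1 of each day 7 group. Alternatives for gene lists were not run, since 0 probes matched a list. Signal over background limits the dim probes, of which 2901 were not tested.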

Other observations

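The tests of 1 outside source, of the slide and of nodules against nitrogen were chosen after the results were seen. Probe IDs differ in prefix, and the prefixes went with the responses. The hypothesis that AG-N sequences are raised in nodules more often than AG-R sequences held: 736 of 3929 AG-N probes (18.7%) and 338 of 3348 AG-R probes (10.1%) were at least 2-fold higher in nodules than at day 0, an odds ratio of 2.05 (Fisher exact p = 1.14e-25, with probes not being independent). Outside the co-varying set AG-R probes were at least 2-fold higher with nitrogen in 24.4% of cases and AG-N probes in 9.08%. The reverse held without nitrogen, with 12.1% of AG-R, 23.2% of AG-N and 30.5% of AG-J probes. What the prefixes stand for is not stated in the files.

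The co-varying set of 305 probes may be RNA from 1 outside source in different amounts, which would shift all its probes by one ratio between arrays. Across its bright probes and 16 pairs of arrays of different groups the SD of the log2 ratio was 0.674, against 1.35 over all other bright probes and 0.330 between replicates, which alder genes regulated together could also give, so this stays open. Words of 3 bases told the set from other probes with an AUC of 0.850, against at most 0.628 for sets raised in nodules, with nitrogen or without it, or drawn at random. RNA of another organism would give this, though an unusual class of alder sequences could do the same. The sets were also unlike: only 180 of the 305 probes had passed the filter, whereas the other sets held tested probes alone. Mean GC content hardly differed, at 40.98% in the set and 41.06% in the other probes. The slide alone cannot have set the level, since in groups not used to choose the set replicates 1 and 2 shared a slide and differed by 2.97 log2 with nitrogen and 2.08 in inoculated roots, and no biological explanation was tested.

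More probes were higher without than with nitrogen, and 2 of the arrays with nitrogen were dim. The brightest array with nitrogen had a 75th percentile of 2652, above that of the 3 non-inoculated arrays at day 7 without nitrogen. On it, 7184 probes called without that array kept 0.932 of their median change, and 63.1% of them were higher without nitrogen. The 2354 called higher without nitrogen by under 2-fold kept 0.942. The difference was thus not limited to the 2 arrays with a lower 75th percentile. Dimness is not excluded, since the median signal of the brightest array, 436, was still below that of the 3 arrays without nitrogen (450, 510 and 491). These 3 arrays had also served to call the probes, of which 4443 were already called higher without nitrogen. The share higher without nitrogen, 63.1% over all calls, was 59.9% with median centring and 54.8% with normexp background correction, which leaves open how much the scaling and the background correction contribute.

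One hypothesis was that nodules share the expression state of roots with nitrogen. The changes correlated with r = 0.0371 across probes, which are not independent, and 60.3% of shared calls went the same way, 49.7% with spike-in scaling. Lower in both were 1993 probes, with 1588 expected for independent lists, and higher in both 803, with 714 expected. The hypothesis was left undecided.

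Other splits of the arrays of each comparison into 3 and 3 gave at most 9 calls for inoculation, against 961, 0 for nodules against day 0, against 6558, 0 for nodules against inoculated roots, against 5694, 1 for nitrogen, against 7473, and 1 for time, against 2622. In each case 1 split of 10, the real one, reached the count, and 10 splits are too few for a share under 0.05.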
